A study of Mus musculus with 8 samples.

How the data were processed

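Bone marrow cells from 8-week-old C57BL/6J mice were differentiated for 7 days in medium conditioned by L929 cells, a source of macrophage growth factor, and messenger RNA levels were measured by RNA sequencing in 8 libraries. The deposited files hold 1 table per library with gene-level FPKM made by the authors (fragments scaled by transcript length and by the fragments of the library), each with a confidence interval and a status. Per the submitters' processing notes, TopHat 1.4.1 and Cufflinks 1.3.0 were used with the mm10 build; the source of the gene models is not stated. Each table has 23838 rows and 23354 gene symbols, and rows that share a symbol were summed. Of 21479 symbols found in GENCODE release M21, the locus of 21351 (99.4%) overlapped.

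Read counts were not used here. The width of the confidence intervals implies 21500000 to 37900000 fragments per library, and 75.7% to 77.4% of low genes (under 60 fragments) then fall within 0.02 of a whole number. These figures served to describe depth and to pick genes with a mean of at least 1000 fragments for tests of depth; the fits of expression did not use them. The lowest depth was in Ern1f/fLyz2-Cre control replicate 2 and the highest in Ern1f/fLyz2-Cre IL-4 replicate 1.

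Groups were taken from the titles. The genotype field of the labels gives Ern1f/f for every library numbered 1 and Ern1f/fLyz2-Cre for every library numbered 2, against the title in 4 libraries, so under that field genotype and replicate number cannot be told apart. The labels do not say what the replicate number marks.

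Values were analysed as log2(FPKM + 1) for the 10934 genes with at least 1 FPKM in at least 2 libraries. A model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (eBayes with trend, two-sided), and genes were called at a Benjamini-Hochberg adjusted p under 0.05. There were 6 comparisons: IL-4 in each genotype, genotype in each treatment, genotype averaged over treatments, and the interaction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

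The replicate number was checked as a pairing. Differences between replicates 1 and 2 correlated across genes between every pair of groups (r = 0.69 to 0.83 over 6 pairs), and the first principal component, 59.0% of the variance, parted the numbers, while the second (23.3%) parted IL-4 from control. The fit without a block was fixed before the data were examined. Counts of called genes and list calls that changed are also given with the number as a block. Values for each set are given for part of these. On simulated data with 200 changed genes, a log2 change of 2 was recovered for 149 genes without the block and 198 with it, with 0 and 10 false calls. A log2 change of 1 was recovered for 0 and 161 genes, with 0 and 14 false calls. The simulation changed only IL-4 in Ern1f/f, at genes with a mean log2 value above 2. Its shift between replicate numbers was the same in every group, and its noise was independent between genes and libraries. The shares recovered therefore do not carry over to genotype, or to differences that vary between the numbers.

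Before the data were examined, 27 gene lists were fixed: pathways of macrophage activation, endoplasmic reticulum stress, lipid and energy metabolism, cell cycle, MHC class II, lysosome, immediate-early and ribosomal protein genes, and cell type markers. Lists with at least 5 tested members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison), with an estimated correlation as an alternative. Without the block this estimate includes the difference between replicate numbers. It was then 0.975 for interferon-stimulated genes and 0.993 for fibroblast markers. With an estimated correlation only the alternative activation list in Ern1f/f cells was called without the block, and no list with it (adjusted p = 0.351 for that list). With fry, which asks whether a list's genes move one way on balance, this list was called in both genotypes (adjusted p = 0.0068 and 0.0076). With the block it was called by fry as well (adjusted p = 0.0292 and 0.0190). No other list was called by fry in any comparison. Without the block each list had an adjusted p by fry of 0.989 for genotype in control cells, 0.967 with IL-4 and 0.993 for the interaction.

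The genes named were chosen by a rule fixed beforehand: up to 12 higher and 12 lower genes past the threshold with the largest differences, a mean of at least 1 FPKM and no overlap between the groups. Where none passed, the 4 higher and 4 lower genes with the smallest p were given. To these came 10 genes of interest and up to 4 members per list. After the data were examined the same rule was applied to the blocked fit. Alternatives covered the pseudocount (0.1 and 5), the filter, scaling, the variance model, rows per symbol, gene status, the block, the genotype field, the samples in the fit and each library left out.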

Results

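The series asked whether IRE1α, the endoplasmic reticulum stress sensor encoded by Ern1, limits the alternative activation of macrophages. Macrophages grown from mouse bone marrow carried a floxed Ern1 gene alone (Ern1f/f) or together with Cre recombinase expressed from the Lyz2 locus, which is active in myeloid cells (Ern1f/fLyz2-Cre). They were left untreated or given IL-4, the cytokine that induces alternative activation, at 20 ng/ml for 24 hours. Each of the 4 groups had 2 libraries, and expression is given as FPKM. The 4 libraries numbered 1 are called set 1 and the 4 numbered 2 are called set 2, since libraries with the same number deviated from their groups together.

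Lyz2, the lysozyme gene that hosts the Cre, was lower in libraries titled Ern1f/fLyz2-Cre than in those titled Ern1f/f within each set. Control cells titled Ern1f/f held 18110 and 17420 FPKM of Lyz2, and those titled Ern1f/fLyz2-Cre held 10950 in set 1 and 2171 in set 2. The corresponding IL-4 libraries held 8901 and 11960 against 5780 and 1572 FPKM. Lyz2 in the Cre libraries therefore stood at 60.4% (control) and 64.9% (IL-4) of the Ern1f/f level in set 1, and at 12.5% and 13.1% in set 2. Averaged over treatments the log2 difference of Lyz2 was -1.82 ± 0.62 (SE) and did not pass the correction. Ern1 itself (chromosome 11, 106397620 to 106487796, mm10) was lower in the Cre library than in its Ern1f/f counterpart only with IL-4 in set 1. Its log2 difference was 0.33 ± 0.20 in control cells and -0.08 ± 0.20 with IL-4 (SE), neither past the correction. It read 11.5 and 9.55 FPKM in Ern1f/f controls, 10.2 and 9.11 with IL-4, 14.3 and 12.7 in Cre controls, and 7.43 and 10.98 in Cre cells with IL-4. A gene-level value cannot show the loss of some exons, so these values do not check the deletion. The genotype field of the labels follows the replicate number and contradicts the title in 4 of the 8 libraries; groups follow the titles throughout.

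**Figure D1:**
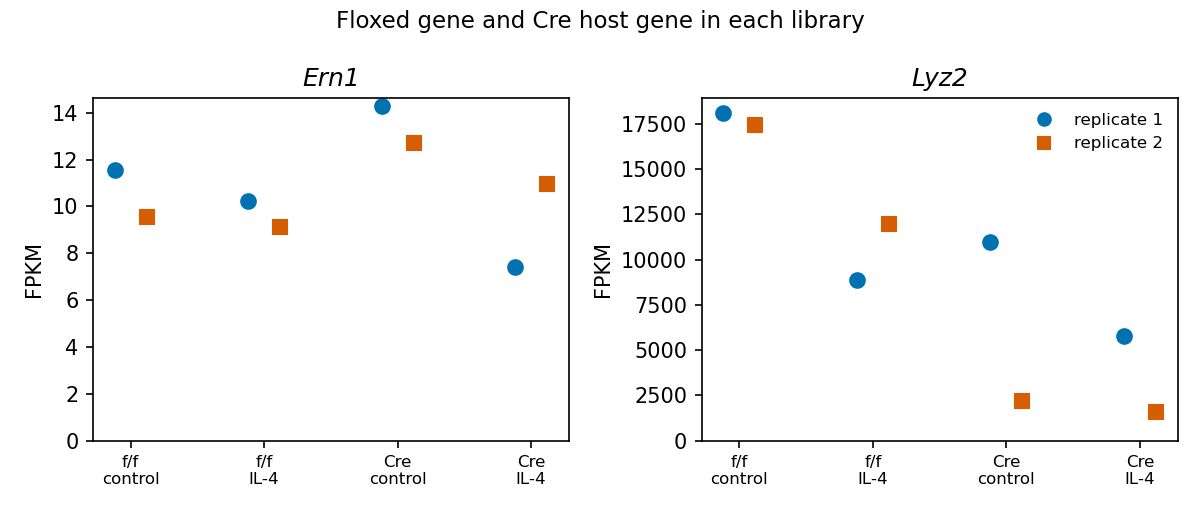
FPKM of Ern1 (left) and Lyz2 (right) on linear axes in each of the 8 libraries, by titled group; circles are replicate 1 and squares replicate 2, 1 point per library. Lyz2 was lowest in the replicate 2 libraries titled Cre (2171 and 1572 FPKM), whereas Ern1 lay between 7.43 and 14.3 FPKM.

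In cells titled Ern1f/f, several marker genes of alternative activation had much higher levels with IL-4 than without it. Arg1, which encodes arginase 1, went from 0.364 ± 0.453 to 68.6 ± 5.24 FPKM (SD, n = 2), a log2 difference of 5.71 ± 0.49 (SE). Cish, a feedback inhibitor of STAT5 signalling, went from 0.752 ± 0.422 to 18.2 ± 2.36 FPKM (log2 3.47 ± 0.25). Mrc1, the mannose receptor, went from 35.1 ± 8.02 to 166 ± 59.5 FPKM (log2 2.18 ± 0.31). Irf4, a transcription factor of this program, went from 0.444 ± 0.0852 to 8.58 ± 3.81 FPKM (log2 2.67 ± 0.28). Further genes with large differences were Mgl2 (log2 4.90), Lipn (log2 2.74), Il4i1 (log2 3.91), Ocstamp (log2 3.84), Pdcd1lg2 (log2 3.49), Tmem26 (log2 3.24) and Slc7a2 (log2 2.89). Ear11 (log2 4.69) has close paralogs whose reads gene-level values may not separate. Lower genes included Apoc2 (log2 -1.78), Tlr2 (log2 -1.48), the haptoglobin gene Hp (log2 -1.46), Pilra (log2 -1.46), S100a8 (log2 -1.44), Gpx3 (log2 -1.27), the iron transporter gene Slc11a1 (log2 -1.15) and Stk17b (log2 -1.06).

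None of the 10934 genes passed an adjusted p of 0.05 by limma without a replicate block, where the smallest was 0.0639; 673 had an unadjusted p under 0.05, against 546.7 expected by chance. With the replicate set as a block, 232 genes passed, 138 higher and 94 lower, and each gene named in the paragraph above was among them. The blocked adjusted p was 0.000511 for Arg1 and Cish, 0.00449 for Mrc1, 0.00653 for Irf4 and 0.0109 for Pilra. The blocked count depends on single libraries: it was 6 and 17 without Ern1f/f control replicates 1 and 2, 21 and 103 without Ern1f/f IL-4 replicates 1 and 2, and 101 and 75 without Ern1f/fLyz2-Cre IL-4 replicates 1 and 2.

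Retnla and Chi3l3, 2 other widely used markers, passed neither fit, and their control levels differed between the sets. Retnla went from 0.323 to 1256 FPKM in set 1 and from 12.1 to 634 FPKM in set 2 (blocked adjusted p = 0.0594). Chi3l3, whose close relatives share sequence, went from 0.844 to 476 FPKM in set 1 and from 999 to 4276 FPKM in set 2 (blocked adjusted p = 0.206). Klf4 had a log2 difference of 1.42 ± 0.33 (blocked adjusted p = 0.069). Xbp1, the messenger RNA that IRE1α splices, differed by 0.03 ± 0.15 on the log2 scale, a measure that does not separate spliced from unspliced transcripts.

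Of the gene lists fixed in advance, alternative activation stood out. Its 31 tested members had a median log2 difference of 2.08 (2.50 in set 1, 1.48 in set 2), and 29 were higher in both sets. None passed over all genes without the block, 21 passed adjusted over the list alone, and 15 passed with the block. By camera the list's adjusted p was 2.83e-35, and 0.0431 with an estimated correlation. With the block and an estimated correlation it was not called by camera (adjusted p = 0.351), while by fry with the block it was (adjusted p = 0.0292). The 10 MHC class II genes were all higher in both sets (median log2 0.77, camera adjusted p = 3.21e-11). H2-DMa (log2 1.05) and H2-DMb1 (log2 1.02), which load peptide onto class II molecules, passed with the block. With an estimated correlation the class II list was not called (adjusted p = 0.34). Cholesterol synthesis genes (24 tested, median log2 0.37, camera adjusted p = 2.29e-07) included Dhcr7, which passed with the block at log2 0.76. Cell cycle genes (28 tested, median log2 0.31; 0.02 in set 1, 0.56 in set 2; camera adjusted p = 2.16e-07) included Pcna, at log2 0.68 with a blocked adjusted p of 0.0848. Oxidative phosphorylation genes (25 tested) had a median of 0.16 (0.33 in set 1, 0.07 in set 2; camera adjusted p = 4.97e-06). Osteoclast markers (5 tested, median log2 0.15; 0.01 in set 1, 0.28 in set 2; camera adjusted p = 0.0113) were led by Ocstamp and Dcstamp (log2 1.90), which act in macrophage and osteoclast fusion. With an estimated correlation the adjusted p of these 4 lists was 0.678, 0.441, 0.566 and 0.441, in the order given.

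The remaining lists were not called by camera in this comparison without the block. Their median log2 differences were 0.06 for classical activation, -0.09 for interferon-stimulated genes, 0.14 for XBP1-dependent endoplasmic reticulum genes, -0.05 for endoplasmic reticulum chaperones, -0.10 for PERK and ATF4 targets and -0.19 for substrates of IRE1-dependent decay. For LXR targets the median was -0.03, for glycolysis 0.07, for lysosome 0.03, for ribosomal proteins -0.05, for macrophage markers -0.04, for monocyte markers -0.32 and for neutrophil markers 0.01. It was -0.0049 for fatty acid oxidation (camera adjusted p = 0.117) and -0.0048 for immediate-early genes (camera adjusted p = 0.356). Fibroblast markers had a median of -0.87 in set 1 and -0.08 in set 2. With the block the XBP1-dependent list was called (camera adjusted p = 0.0435; 0.998 with an estimated correlation). Only 2 of 8 B cell markers and 1 of 9 T or NK cell markers reached 1 FPKM in 2 libraries, and 0 of the 9 dendritic, 9 mast cell and 9 erythroid markers in the tables, so these lists were not tested.

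**Figure D2:**
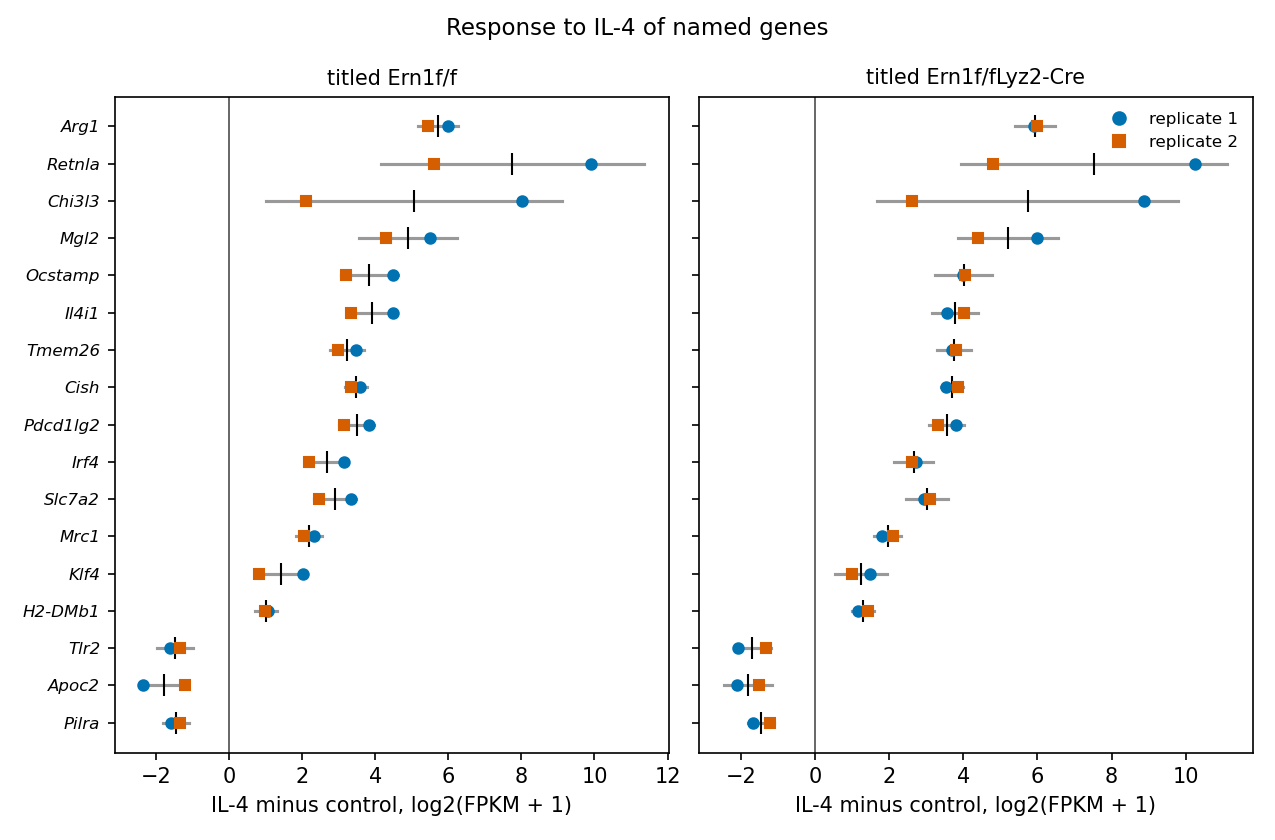
Log2(FPKM + 1) difference of IL-4 minus control for 17 named genes in libraries titled Ern1f/f (left) and Ern1f/fLyz2-Cre (right); circles are set 1, squares set 2, vertical ticks the mean of both and grey lines the 95% confidence interval of the blocked limma fit. Arg1 lay at 5.71 and 5.94, and the sets lay farthest apart for Chi3l3 and Retnla.

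In cells titled Ern1f/fLyz2-Cre, IL-4 raised Arg1, Cish, Tmem26, Ocstamp, Slc7a2 and Clec4b1. Arg1 rose from 0.607 ± 0.772 to 98.9 ± 51.8 FPKM (SD, n = 2; log2 5.94 ± 0.49, SE). Ocstamp rose by log2 4.01 ± 0.35, Tmem26 by 3.76 ± 0.30 and Cish by 3.69 ± 0.25. Slc7a2, a transporter of arginine, rose from 6.54 ± 1.68 to 59.7 ± 9.34 FPKM (log2 3.02 ± 0.26). Clec4b1, a C-type lectin gene, rose from 3.74 ± 0.0989 to 15.9 ± 0.849 FPKM (log2 1.84 ± 0.14). These 6 genes, each with an adjusted p of 0.0490, were the only ones of 10934 to pass limma without the block, and 933 had an unadjusted p under 0.05.

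With the replicate block 363 genes passed, 196 higher and 167 lower. They included Mgl2 (log2 5.20), Rbp4 (log2 3.36), Mrc1 (log2 1.96) and, among lower genes, Slc40a1, the iron exporter ferroportin (log2 -1.94), F13a1 (log2 -1.70), Tlr2 (log2 -1.69), Socs3 (log2 -1.55) and Cebpd (log2 -1.42). Leaving out single libraries moved both counts: the 6 became 0 or 1 without any 1 library, and the blocked 363 became 7 and 2 without Ern1f/fLyz2-Cre IL-4 replicates 1 and 2, 68 and 141 without the Cre control replicates, and 168 and 163 without the Ern1f/f control replicates. The 6 also became 0 with a pseudocount of 0.1, with no filter on low values, without the trend and with only the compared groups in the fit.

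The alternative activation list again led, with a median log2 difference of 1.81 (2.34 in set 1, 1.53 in set 2). Of its 31 members, 3 passed over all genes and 21 adjusted over the list alone. Its camera adjusted p was 1.32e-25, but 0.079 with an estimated correlation. MHC class II genes had a median of 1.01 (camera adjusted p = 7.62e-10; 0.311 with an estimated correlation), and H2-DMb1 had a log2 difference of 1.29 (blocked adjusted p = 0.0077). Of the 25 oxidative phosphorylation genes, 24 were higher in both sets, with a median of 0.44 (camera adjusted p = 8.13e-13; 0.311 with an estimated correlation). Sdhd was among them at log2 0.49. Cholesterol synthesis (median 0.37; 0.10 in set 1, 0.67 in set 2; camera adjusted p = 9.45e-07), XBP1-dependent endoplasmic reticulum genes (0.16, 0.00244), ribosomal proteins (0.17, 0.000348), cell cycle genes (0.18; 0.10 in set 1, 0.28 in set 2; 0.00678) and fatty acid oxidation (0.10, 0.0296) were called higher, each with an adjusted p of 0.611 with an estimated correlation. The fatty acid oxidation medians differed in sign, with -0.02 in set 1 and 0.22 in set 2. The disulfide isomerase gene Pdia4 (log2 1.29) and Creld2 (log2 0.74) were the XBP1-dependent genes past the blocked threshold. Classical activation genes were called lower (median -0.98, camera adjusted p = 0.0132; 0.72 with an estimated correlation), with medians of -1.65 in set 1 and -0.17 in set 2. Glycolysis genes Pfkl (log2 -0.80) and Slc16a3 (log2 -1.05) were lower in the blocked fit, while their list was not called. Osteoclast markers had a median of 0.41 (camera adjusted p = 0.0316; 0.572 with an estimated correlation). Fibroblast markers had a median of -0.98 in set 1 and -0.06 in set 2.

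The 2 responses overlapped. In the blocked fits 127 genes were higher in both genotypes, against 2.47 if the calls were independent, and 78 were lower in both, against 1.44. No gene was called in opposite directions. Across genes, the IL-4 differences of the 2 genotypes correlated at r = 0.793 in set 1 and 0.524 in set 2; genes are not independent replicates.

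Whether the response to IL-4 differed by genotype was tested as an interaction, and no gene passed. For Arg1 the response of Cre cells minus that of Ern1f/f cells was 0.23 on the log2 scale (95% confidence interval -1.46 to 1.93 without the block, -0.54 to 1.002 with it). For Mrc1 it was -0.22 (-1.30 to 0.85; -0.73 to 0.28 with the block) and for Irf4 -0.01 (-0.98 to 0.96; -0.76 to 0.74). For Retnla it was -0.22 (-7.33 to 6.89; -5.31 to 4.87 with the block), with 0.35 in set 1 and -0.79 in set 2. Intervals without the block include the differences between the sets. The alternative activation list had a median of 0.03 and was not called. By limma 19 genes had an unadjusted p under 0.05 without the block and 103 with it, both far below the 546.7 expected by chance. The lack of called genes therefore does not show that the responses were equal. Without the block these intervals leave room for differences of about 1 log2 unit in either direction for Mrc1 and Irf4, and the blocked intervals are narrower.

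Some lists did differ by camera with its preset correlation of 0.01, though none did by fry (adjusted p = 0.993 for each). The estimated correlation was 0.22 for ribosomal protein genes, 0.29 for oxidative phosphorylation and 0.38 for classical activation. These estimates come from the fit without the block and include the difference between the sets. Ribosomal protein genes responded higher in Cre cells by a median of 0.24, with 37 of 40 higher in both sets (camera adjusted p = 8.99e-14; 0.45 with an estimated correlation). Examples were Rps23 at 0.53 and Rpl22 at 0.35. Oxidative phosphorylation genes did so by 0.19 (camera adjusted p = 7.64e-09; 0.472 with an estimated correlation), with Cox7a2 at 0.57. Classical activation genes responded lower, with a median of -0.64 (camera adjusted p = 1.84e-06; 0.58 with an estimated correlation). That median was -1.10 in set 1 and 0.00 in set 2. Among these genes, Cre control replicate 1 held 58.7 FPKM of Il1b against 2.09 to 7.30 in the other 7 libraries. XBP1-dependent genes had a median of 0.12 (-0.04 in set 1, 0.20 in set 2; camera adjusted p = 0.0445), a call that ended with the block (adjusted p = 0.065). Interferon-stimulated genes (median -0.12; -0.29 in set 1, 0.12 in set 2) were called lower with the block alone (adjusted p = 0.010; 0.914 with an estimated correlation). Immediate-early genes had a median of -0.18 (camera adjusted p = 0.0223; 0.45 with an estimated correlation). Genes with the smallest p included Hist1h4k (-1.34), Hist1h4b (-1.64), Gvin1 (-1.03), Cdk6 (-0.48), Snapc5 (0.63) and Lenep (0.84), given as values.

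**Figure D3:**
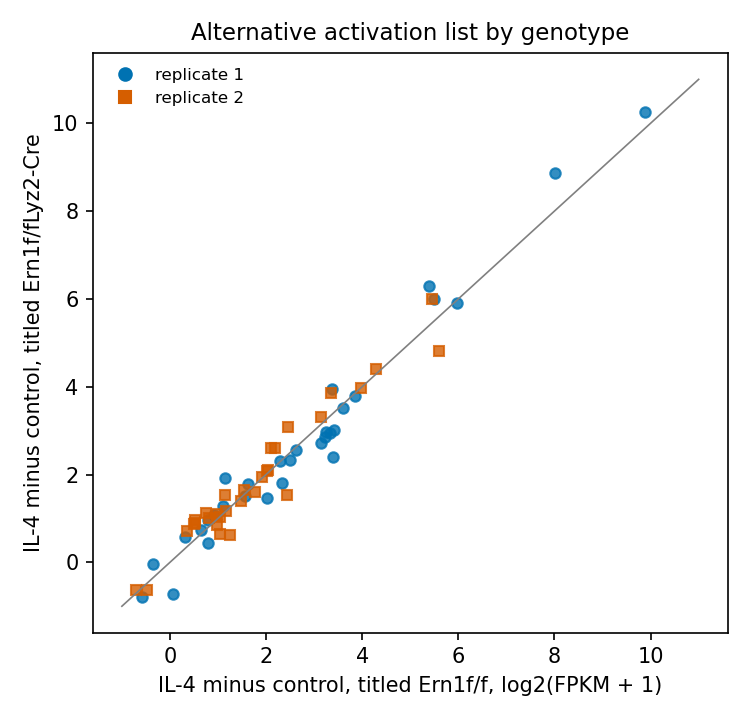
Log2(FPKM + 1) difference of IL-4 minus control for the 31 alternative activation genes in libraries titled Ern1f/f (x axis) and Ern1f/fLyz2-Cre (y axis); circles are set 1, squares set 2, and the line marks equal differences. The points follow the line; the median difference between genotypes was 0.03.

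In control cells, no gene passed for genotype by limma without or with the block. An unadjusted p under 0.05 was found for 27 genes without it and 137 with it. Both counts lay far below the 546.7 expected by chance. With counts below chance, the lack of called genes does not show that genotype had no effect. Among alternative activation markers, Arg1 differed by 0.19 ± 0.49, Mrc1 by 0.40 ± 0.31, Retnla by 1.32 ± 2.06, Slc7a2 by -0.63 ± 0.26 and Mgl2 by -0.60 ± 0.59 on the log2 scale (SE). The last 3 differed mainly in set 2, where they read 2.76, -1.13 and -1.21, against -0.11, -0.13 and 0.01 in set 1. The genes with the smallest p were, on the higher side in Cre libraries, F13a1, a coagulation factor gene (2.49 ± 1.17 against 8.27 ± 0.267 FPKM, SD, n = 2; log2 1.45), Bex1 (log2 0.87), Steap3 (log2 0.61) and Zcchc24 (log2 0.49). On the lower side they were Snhg9 (log2 -2.81), Hist2h2bb (log2 -0.88), Ass1 (log2 -0.53) and Clec4b1 (log2 -0.40). None of these 8 differences passed the correction.

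MHC class II genes had a median of -0.31 in Cre control cells (camera adjusted p = 6e-11; 0.589 with an estimated correlation), with -0.62 in set 2 and -0.09 in set 1. Cd74, the invariant chain, differed by -0.52 and H2-Aa by -0.61. XBP1-dependent genes had a median of -0.11 (0.02 in set 1, -0.26 in set 2; camera adjusted p = 5.94e-07), with Dnajb9, a chaperone gene, at -0.31. Glycolysis genes had a median of 0.14 (camera adjusted p = 5.7e-06), cell cycle genes 0.09 (0.00172), oxidative phosphorylation genes -0.08 (0.000824), ribosomal protein genes -0.06 (0.00397) and classical activation genes 0.40 (0.00042). Each of these 6 lists had an adjusted p of 0.589 with an estimated correlation. The oxidative phosphorylation median was 0.05 in set 1 and -0.20 in set 2. The classical activation median was 1.13 in set 1 and -0.24 in set 2, and Il1b (log2 1.24) turned to -0.65 without Cre control replicate 1 and was 3.13 without replicate 2. Fibroblast markers had medians of 1.15 in set 1 and -0.25 in set 2, and were called higher with the block alone (camera adjusted p = 0.0143; 0.734 with an estimated correlation). Also called with the block alone were monocyte markers (median 0.05; 0.16 in set 1, -0.05 in set 2; adjusted p = 0.0152) and immediate-early genes (0.05; 0.02 and 0.22; 0.0478). So were osteoclast markers (-0.16; -0.07 and -0.09; 0.0478), each of these 3 with an adjusted p of 0.634 with an estimated correlation. LXR targets were called too (0.10; 0.15 and 0.00; 0.0373), at 0.687 with an estimated correlation.

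Among IL-4-treated cells, no gene passed for genotype without the block (42 had an unadjusted p under 0.05, against 546.7 expected by chance). Arg1 differed by 0.42 ± 0.49 and Retnla by 1.10 ± 2.06 on the log2 scale (SE). Genes with the smallest p were Insl3 (log2 0.97), Bex1 (log2 0.93), Cox7a2 (log2 0.52) and Uchl3 (log2 0.52), higher in Cre libraries, and Cdk6 (log2 -0.38), Pdgfb (log2 -0.37), Idua (log2 -0.35) and Nbeal2 (log2 -0.32), lower. With the block 189 genes had an unadjusted p under 0.05 and 1 passed the correction: H2-L, a class I histocompatibility gene, with a log2 difference of -1.88 (adjusted p = 0.032). H2-L went from 476 to 143 FPKM in set 1 but from only 4.98 to 0.460 in set 2, and its relatives share sequence. Ribosomal protein genes had a median of 0.18, with 35 of 40 higher in both sets (camera adjusted p = 6.13e-12), and oxidative phosphorylation genes had a median of 0.11 (2.52e-05). MHC class II genes had a median of -0.31 (0.000183). These 3 lists had an adjusted p of 0.674 with an estimated correlation. Classical activation (-0.26, camera adjusted p = 0.00637), LXR targets (0.15, 0.0413) and cholesterol synthesis (0.13, 0.0192) were also called, at 0.789, 0.789 and 0.969 with an estimated correlation. Fatty acid oxidation (0.12; 0.05 in set 1, 0.14 in set 2) was called with the block alone (adjusted p = 0.0461; 0.947 with an estimated correlation). Fibroblast markers had medians of 1.03 in set 1 and -0.19 in set 2, and LXR targets had medians of -0.03 in set 1 and 0.30 in set 2.

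Averaged over treatments, 4 libraries against 4, no gene passed for genotype without or with the block. An unadjusted p under 0.05 was found for 52 and 223 genes, against 546.7 expected by chance. The labels do not say whether the control and IL-4 libraries of 1 genotype and set share a source. The 4 libraries of a genotype may therefore not be independent. The smallest p belonged to F13a1 (log2 1.04 ± 0.18, SE), Bex1 (0.90 ± 0.20), Steap3 (0.52 ± 0.13) and Slc39a14 (0.34 ± 0.09), higher in both sets, and to Hist2h2bb (-0.59), Idua (-0.37), Slc9b2 (-0.41) and Ass1 (-0.36), lower in both sets. MHC class II genes had a median of -0.33 (-0.10 in set 1, -0.54 in set 2; camera adjusted p = 6.27e-12; 0.591 with an estimated correlation). Glycolysis (0.10, camera adjusted p = 0.000139), XBP1-dependent genes (-0.08, 5.3e-05) and LXR targets (0.10, 0.00633) had an adjusted p of 0.694 with an estimated correlation. Ribosomal protein genes (0.05, camera adjusted p = 0.0022) and cholesterol synthesis (0.09, 0.0051) reached 0.918 and 0.966. Substrates of IRE1-dependent decay, which loss of the enzyme would spare, had a median of 0.15 (0.23 in set 1, -0.07 in set 2) and were not called. Hgsnat, 1 of them, differed by 0.57, and the list also holds stromal genes such as Sparc and Col6a1. Fibroblast markers had medians of 1.09 in set 1 and -0.20 in set 2, and were called higher with the block alone (camera adjusted p = 0.0185; 0.924 with an estimated correlation).

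The sets did not share their genotype differences: across genes these correlated at r = -0.22 between set 1 and set 2. With genotype and treatment as terms, set 1 alone gave 404 genes and set 2 alone gave 512, fits with 1 residual degree of freedom. Of the 404 genes, 216 were lower in set 2 than in set 1 by log2 1 or more, as were 359 of all 10934. Of the 8 tested fibroblast markers, 7 were called in set 1 and 2 in set 2. Within a set each genotype has 1 control and 1 IL-4 library, which may share a source. These calls may then reflect the source as well as the genotype. Of 108 genes called in both, against 18.9 if the calls were independent, 15 had the same direction, F13a1, Bex1 and Fn1 among them. In the same fits IL-4 was called for 3094 genes in set 1 and 2397 in set 2, and of 1386 called in both, 1305 had the same direction. Among genes that went opposite ways, Col1a1 was higher in Cre libraries by 1.55 in set 1 and lower in set 2 (-1.11). Col1a2 differed by 1.39 and -0.95, and Sparc by 1.52 and -1.07. Their set 2 levels were near the filter of 1 FPKM. Col1a1 lay at 0.444 to 2.60 FPKM there, Col1a2 at 0.475 to 2.08 and Sparc at 0.774 to 3.44. Col1a1 and Col1a2 were the only 2 of the 8 tested fibroblast markers called in both sets. Fn1, Col1a1, Col1a2 and Sparc were chosen after their values were seen.

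**Figure D4:**
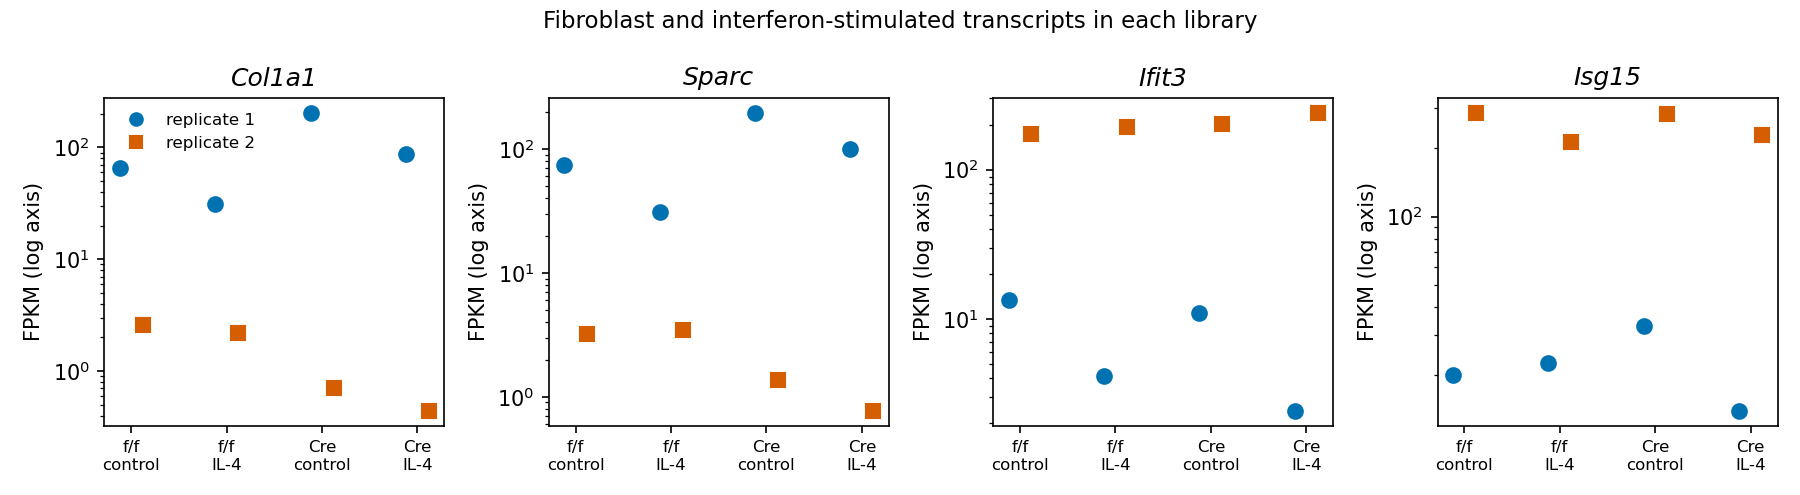
FPKM on log axes of Col1a1 and Sparc (fibroblast transcripts) and of Ifit3 and Isg15 (interferon-stimulated) in each of the 8 libraries, by titled group; circles are replicate 1 and squares replicate 2. Col1a1 lay at 31.1 to 203 FPKM in set 1 and at 0.444 to 2.60 in set 2, and Ifit3 at 2.44 to 13.5 and 172 to 240.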

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

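All tests of this part except the interaction itself were chosen after the values were seen. In 6 gene lists the response to IL-4 differed between genotypes by the interaction term in camera without the block. The median difference of Cre minus Ern1f/f responses was -0.64 for classical activation, 0.12 for XBP1-dependent endoplasmic reticulum genes, 0.19 for oxidative phosphorylation, -0.10 for the cell cycle, -0.18 for immediate-early genes and 0.24 for ribosomal proteins. None of the 6 was called with an estimated correlation (adjusted p of 0.58, 0.928, 0.472, 0.928, 0.45 and 0.45). By fry none of the 6 was called either (adjusted p = 0.993 for each). With the replicate block the XBP1-dependent list was no longer called (adjusted p = 0.065), and interferon-stimulated genes were (0.010). Medians of the sets had opposite signs for XBP1-dependent genes (-0.04 and 0.20) and the cell cycle (0.16 and -0.39). For classical activation the difference came from set 1 alone (-1.10, against 0.00 in set 2).

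Single genes went opposite ways in both sets, a property that was not tested. They were picked by these signs from the genes named here, and the number that signs alone would give was not computed. Cxcl1 was higher with IL-4 in Ern1f/f cells (0.30 and 0.31) and lower in Cre cells (-1.72 and -0.04), a gap of -1.19. That gap was -2.02 in set 1 and -0.35 in set 2. By genotype, Clec4b1 was lower in Cre control cells (-0.53 and -0.28) and higher with IL-4 (0.13 and 0.21), a gap of 0.57. Rps23 (gap 0.53) and Rpl22 (gap 0.35) had the same signs. Their control differences were small (-0.05 and -0.10 for Rps23, -0.04 and -0.07 for Rpl22). With IL-4 they were 0.56 and 0.33 for Rps23, and 0.28 and 0.32 for Rpl22.

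Lyz2 was lower in libraries titled Cre, and far more so in set 2 than in set 1. A lower share of macrophages would lower the other macrophage markers too, but in set 2 these 12 genes had a median of 0.256 (SD 0.352) against -2.97 for Lyz2. In set 1 they had a median of -0.176 (SD 0.114) against -0.67 for Lyz2; 11 of the 12 were lower there and fibroblast markers were higher (1.09), so a lower share may account for part of the set 1 difference but not for all of it. Reads moving to the neighbouring paralog Lyz1 would appear there, but Lyz1 changed by -0.1% of the FPKM that Lyz2 lost, 1.08% in set 1 and -0.572% in set 2. Lyz1 itself was called in both sets in opposite directions, higher in Cre cells by 1.35 in set 1 and lower in set 2 (-1.59). The number of Cre alleles stays open: Lyz2 stood at 12.8% of the Ern1f/f level in set 2 and 62.7% in set 1, and the labels do not give the copies carried. No biological explanation was tested.

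Genotype differences did not repeat between the sets. Shallow sequencing would spare well-covered genes, but over the 4993 genes with a mean of at least 1000 fragments the correlation between sets was -0.269. Stromal cells may contribute: without the 359 genes lower in set 2 by log2 1 or more, the correlation was -0.187 against -0.222. This cannot decide, since a gene made by both cell types is not removed. A first version of this test, which counted calls in set 2 (512, against 404 in set 1), was set aside because 2 of 8 fibroblast genes were called there too. The real split gave 0 genes, so each of the 18 splits of the 8 libraries that balance treatment had to give at least as many, and the count says nothing about chance. With 18 splits no share under 0.05 is possible either. The highest other, the split by replicate number, gave 5240. That split points to a structure of the samples by replicate number; among the 8 splits with 1 library of each number per treatment, the highest other gave 1 gene, and at an unadjusted p under 0.05 the real split gave 52 genes and the highest other 90.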

How the results depend on the processing

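Most alternatives were fixed beforehand; the alternatives of the blocked fits and the fits within each set were added after the data were examined. IL-4 in Ern1f/f cells, 0 genes as reported, gave 11 with median ratio scaling, 232 with the replicate block, 2264 with the genotype field, and 0 to 1 leaving out each library. IL-4 in Ern1f/fLyz2-Cre cells, 6 genes as reported, gave 0 with a pseudocount of 0.1, without a filter, without the trend and with only the compared groups, 22 at 5 FPKM or more, 21 with median ratio scaling, 18 with quantile normalization, 363 with the block, 1273 with the field, and 0 to 1 leaving out each library. With the block, leaving out each library gave 6 to 277 and 2 to 325 genes. Genotype gave 3816 genes in control cells, 3273 with IL-4, 5240 averaged and 106 for the interaction with the genotype field, under which genotype is the replicate number. With the block, genotype in IL-4 cells gave 1. Averaged genotype gave 1289 in the 4 libraries whose labels agree, Ern1f/f of set 1 against Cre of set 2, where genotype is again the replicate number, and 404 and 512 within set 1 and set 2. The remaining alternatives kept each count on its side. The cause was not tested, except that the field and the agreeing labels turn genotype into the replicate number and left-out libraries leave fewer samples.

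Single genes that turned with the genotype field were, in control cells, Chi3l3 (9.34), Col5a1 (-3.25), Ern1 (-0.20), Il1b (-2.06), Mgl2 (0.74), Mrc1 (-0.46), Postn (-4.01) and Zcchc24 (-0.25), with IL-4, Clec10a (-0.39), Irf4 (-0.54) and Klf4 (-0.62), averaged, Mrc1 (-0.46), and for the interaction, Chi3l3 (-6.09), Ern1 (0.38) and Il1b (1.89). Mrc1 averaged was -0.18 in the 4 libraries whose labels agree, and Il1b in control cells was -0.65 without Cre control replicate 1 and 3.13 without replicate 2. Depth limits genes near 1 FPKM most, and 2 libraries per group limit every comparison.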

Other observations

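The 2 replicate sets differed in many genes. With all 4 groups in each set, 4 libraries against 4, 3657 of 10934 genes passed limma between them, 1104 higher and 2553 lower in set 2. All 28 interferon-stimulated genes passed and were higher in set 2, with a median log2 difference of 2.21 (camera adjusted p = 2.97e-30; 0.672 with an estimated correlation). Isg15, a ubiquitin-like antiviral gene, read 14.0 to 33.0 FPKM in set 1 and 214 to 286 in set 2, and Mx1 0.932 to 2.72 against 31.2 to 64.6. The monocyte chemokine Ccl8 read 0.873 to 3.42 FPKM in set 1 and 250 to 513 in set 2, the transporter Slc13a3 2.41 to 9.95 against 431 to 806, and the scavenger receptor Marco 3.36 to 17.5 against 194 to 412.

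All 8 fibroblast markers passed and were lower in set 2 (median log2 -2.89, camera adjusted p = 0.000133; 0.757 with an estimated correlation). Timp1 read 39.4 to 192 FPKM in set 1 and 1.21 to 3.54 in set 2. Within set 1 Timp1, Col1a1 and Sparc were all highest in Cre control cells and lowest in Ern1f/f cells with IL-4. The bone matrix gene Ibsp reached 4.60 FPKM in set 1 and at most 0.0309 in set 2. Other lists moved as well. Classical activation genes were higher in set 2 (median log2 1.03, camera adjusted p = 9.64e-07), as were neutrophil markers (0.47, 0.0365), PERK and ATF4 targets (0.22, 0.0365), glycolysis (0.10, 0.0103) and alternative activation (0.04, 0.0391). With an estimated correlation their adjusted p was 0.757, 0.672, 0.908, 0.867 and 0.867. Macrophage markers had a median of -0.55, with 7 of 12 passing as lower in set 2 and 2 as higher, and were not called by camera (adjusted p = 0.262). Genes of these 2 paragraphs outside the fixed lists were chosen after their values were seen.

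Of the tests of this difference, the percentage for depth was written before its value was seen and the others after. Of the 4993 genes with a mean of at least 1000 fragments, 4.73% (236 genes) were called with a log2 difference of at least 1, under the 5% set beforehand as the most that depth would give. That bound does not decide, since depth should move almost none of these genes and the share over all genes was only 6.26%. The Ern1f/f control libraries argue against depth: at 30900000 and 31000000 implied fragments, their difference remained. Over the 2467 genes called without these 2 libraries it had a median of 85.9% of the mean of the other 3 pairs (lower quartile 56.2%), and 95.1% had the same direction. Over all 3657 genes, whose choice includes this pair and so favours a high value, the median was 95.6% (lower quartile 68.4%). In the interferon-stimulated part, the 25 members with a mean of at least 1000 fragments had a median of 2.08 (SD 1.14). That mean includes set 2, where they are high, and the test was written after this was seen. The value therefore does not decide about depth. Wrong titles would put the Cre into the Ern1f/f libraries of set 2, but Lyz2 there differed from set 1 by a mean of 0.185 (-0.06 and 0.43). Stromal cells are a candidate source of the fibroblast part: its members correlated at a mean r of 0.954 over the 4 libraries of set 1 (95th percentile of 1000 random lists, 0.282), with Col1a1 up to 203 FPKM and no sort stated in the labels. Stromal cells in set 1 would not lower macrophage markers in set 2, so they leave that part unexplained. The libraries differ by group, so shared regulation is not excluded, and no biological explanation was tested.

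Other values were chosen after they were seen. Ifi202b read 16.7 and 18.1 FPKM in the set 1 libraries titled Cre and at most 0.0205 in the other 6. H2-L read 143 to 476 FPKM in set 1 and 0.460 to 4.98 in set 2. The pseudogene Rps15a-ps6 read 66.4 to 116 FPKM in set 1 and 0.941 to 1.90 in set 2. Cathepsin E (Ctse) was higher in Cre cells by 2.50 in set 1 and lower in set 2 (-0.83). Whether all libraries share the stated strain was not tested.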
